A study of Mus musculus and Arvicanthis niloticus with 12 samples.

How the data were processed

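The series measured messenger RNA of the olfactory epithelium, the tissue of the nose that holds the olfactory sensory neurons, in the laboratory mouse and in the Nile rat (Arvicanthis niloticus, a day-active rodent). There were 12 libraries, 1 for each combination of species, sex and age (8, 12 or 16 weeks), prepared with a stranded messenger RNA kit per the labels' protocols. They were grouped by species and sex into 4 groups of 3 libraries, with 1 library of each age in a group. The labels used here do not say whether a library came from 1 animal or from a pool. They also do not say at what time of day the tissue was taken, or in which batch a library was sequenced. The p-values of single genes therefore measure the spread between these libraries. With 1 library per combination, that spread includes departures from a linear age change and differences in it between the sexes.

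The deposited values are a signal per gene. The authors' name for it, normalized TPM (a length-scaled transcript abundance), comes from the deposited tables. Per the submitters' processing notes, fastp 0.22.0 and kallisto 0.46.1 were used, with a mouse build as the only genome named. How the TPM were scaled further is not given in the sources used here. In units of 1000, the libraries sum to 868 to 1317 in mouse and to 903 to 1310.04 in Nile rat, and plain TPM would give each library the same sum. Read depth is unknown from such values, and no interval or detection floor was computed from it. An exact 0 is described only as a gene listed at 0.

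Of 22468 mouse gene IDs, 22361 were matched to a symbol. Of the 22330 Nile rat IDs, 0 were matched, and the species shared 0 IDs, so no gene could be paired between species. The fit planned over all 12 libraries, the contrasts between species, their interactions and the species comparison of odorant receptors were therefore not run. Each species was fitted alone, and lists of genes were tested in mouse only. Gene coordinates are not reported because the reference used here is another mouse build than the one named in the notes.

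Values were analysed as log2(signal + 1), so fold changes are on that scale and understate the change of low genes. Genes with a signal of at least 1 in at least 3 of the 6 libraries of a species were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend). The model held sex and a linear age term, given as the change from 8 to 16 weeks. Benjamini-Hochberg adjusted p-values under 0.05 were called. The 31 gene lists of cell types, tissues and pathways were fixed before the data were examined, as were the symbol patterns for receptor families. The 33 lists with at least 3 tested genes were tested with limma's camera, with a preset correlation between genes of 0.01 and again with an estimated correlation. With the preset correlation, camera's p rests on the spread of statistics across genes and does not measure the spread between libraries. The estimated correlation was far larger for some lists, such as 0.91 for antigen presentation. A class I receptor list could not be formed from the symbols used. Sums over odorant receptors were compared between sexes by a two-sided exact permutation test, whose smallest possible p for 3 against 3 is 0.1.

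The rule for named genes was part of the same choices. It took, in each direction, up to 10 genes of largest change past the threshold, with a mean of at least 10 in a group compared (over the species for age), a value above 0 in every library and no overlap between the groups, leaving out gene models without a gene symbol. Where fewer than 5 passed, it took the 5 of smallest p under the same limits, as values and not as changes. It added from each list up to 4 members past the threshold, or else the member of smallest p, together with the sex chromosome genes, a fixed set of odorant signalling and clock genes, and the 5 odorant receptors of highest mean. Genes named outside this rule are marked as chosen after their values were seen.

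The test was checked on simulated data with the real gene means, normally distributed noise with spreads as smoothed by limma, and 200 genes changed by 2-fold to 8-fold. For the mouse age term, run on 14662 genes, 71.4% of 2-fold and 100% of 4-fold changes were recovered with 13 false calls. For the mouse sex term these shares were 82.5% and 100%, with 24 false calls. For the Nile rat, run on 14878 genes, 95.3% of 2-fold changes by sex and 89.1% by age were recovered, with 12 and 17 false calls. These simulations assume genes that vary independently, which real libraries need not. Many planted changes also ease the adjusted threshold, so these shares do not carry over to data with few changes. In the real mouse data Nr4a1 had a log2 change of 2.14 with age and was not called (limma adjusted p = 0.0934).

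The alternatives tried were another pseudocount, other filters on low values, quantile normalization, median-ratio scaling, age left out or as a factor, and leaving out each library. Chosen after the data were seen were rescaling each library to the same total, a correction for GC content and transcript length with splines of 4 degrees of freedom (99.9% of tested mouse genes had a value), leaving out libraries with the tested genes held fixed, age as a factor for the age results, and all list tests in mouse alone. Figures were drawn with matplotlib 3.10.9.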

Results

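The data were 12 libraries of olfactory epithelium from mice and Nile rats of both sexes at 8, 12 and 16 weeks. Between 14487 and 14704 mouse genes and between 14670 and 14811 Nile rat genes had a signal of at least 1. Libraries of a species correlated at a Pearson r of 0.97 to 0.99 across genes, and genes are not independent replicates. The design asks how expression in this tissue differs between the sexes and over these ages, within each species.

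Markers of the olfactory sensory neuron were abundant in every mouse library. Omp, the olfactory marker protein of mature neurons, had a mean signal of 3251 ± 812 in males and 2844 ± 214 in females (SD, n = 3 each). The transduction genes Cnga2, a subunit of the odorant-gated channel, Gnal, the olfactory G protein, and Adcy3, the olfactory adenylyl cyclase, had male means of 393.4, 566.5 and 274.3 and female means of 391.0, 567.4 and 252.8. Of 1103 odorant receptor genes, 697 to 806 had a signal of at least 1 per library. The highest were Olfr536 at 110.6 ± 23.01, Olfr533 at 83.1 ± 4.998, Olfr1507 at 78.0 ± 25.6, Olfr727 at 77.7 ± 30.96 and Olfr1348 at 45.04 ± 10.09 (SD, n = 6). The receptors summed to 4520 ± 320.3 in males and 4501 ± 304.2 in females, and the number detected was 744 ± 55.9 and 766 ± 33.8. Neither differed beyond the spread between libraries (two-sided exact permutation p = 1 and p = 0.7, n = 3 each, smallest possible p = 0.1).

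A few genes took a large part of the signal in 1 library of each species. In the 12-week female mouse the 10 highest genes held 27.8% of the signal, against 10.9% to 13.6% in the other mouse libraries. The 17 listed odorant-binding lipocalins found by symbol, secreted carriers of small hydrophobic molecules, made up 9.03% of the signal there and 0.127% to 0.890% elsewhere. Obp1a stood at 42744 and Obp1b at 51027 in that library, against at most 2947 and 3253 in any other. Both genes were named after their values were seen. In the 8-week male Nile rat the 10 highest genes held 27.8%, against 15.1% to 19.1% in the other libraries.

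**Figure D1:**
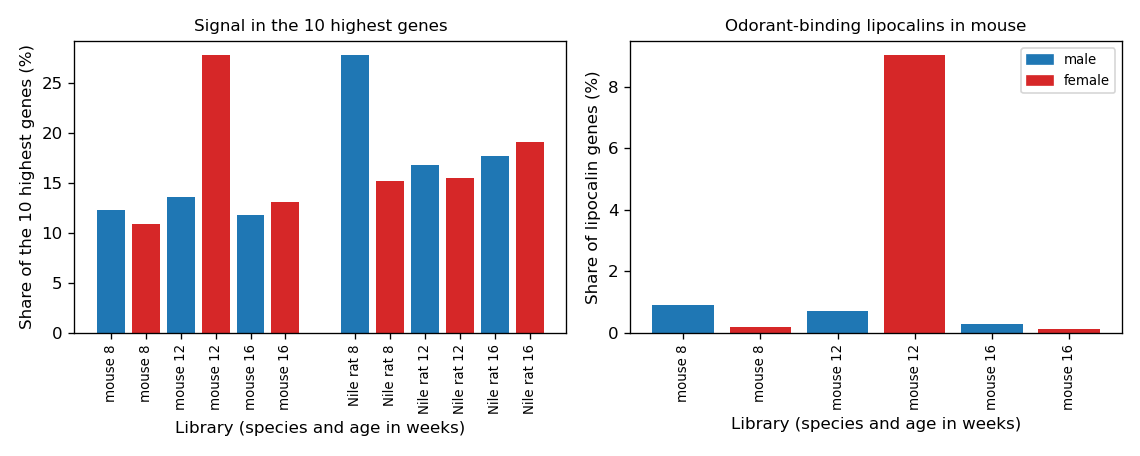
The left panel shows the percentage of each library's signal held by its 10 highest genes, for 6 mouse and 6 Nile rat libraries, and the right panel the percentage held by odorant-binding lipocalins in mouse. Bars are single libraries coloured by sex, and the 12-week female mouse stands at 27.8% and 9.03%.

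Between the sexes in mouse, 3 Y-linked genes were higher in males and 0 genes were higher in females among 14662 tested. Eif2s3y, a translation initiation factor subunit, had a male mean of 42.4 ± 5.56 (limma adjusted p = 7.03e-05). Ddx3y, an RNA helicase, had 22.0 ± 8.42 (adjusted p = 0.00849), and Kdm5d, a histone demethylase, 6.26 ± 1.71 (adjusted p = 0.0118, SD, n = 3). All were listed at 0 in the 3 female libraries. Uty, also annotated on the Y chromosome, had 63.5 ± 14.9 in males and 53.0 ± 10.04 in females and did not separate the sexes. Adjusted over the list alone, 6 of the 8 tested sex chromosome genes passed, adding the X-linked Kdm6a, Eif2s3x and Kdm5c, which were lower in males by log2 changes of -0.71, -0.60 and -0.40. Adjusted over all genes tested, 3 passed. At an unadjusted p under 0.05 there were 256 genes, 1.75% of those tested. Ddx3y and Kdm5d lost their call without the 8-week or the 12-week female library, where 1 gene was called, and 5 genes were called without the 16-week female. Without any 1 male library the Y-linked genes no longer met the filter on low values and 0 genes were called in limma (176 to 630 at an unadjusted p under 0.05), while with the tested genes held fixed all 3 were called each time.

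**Figure D2:**
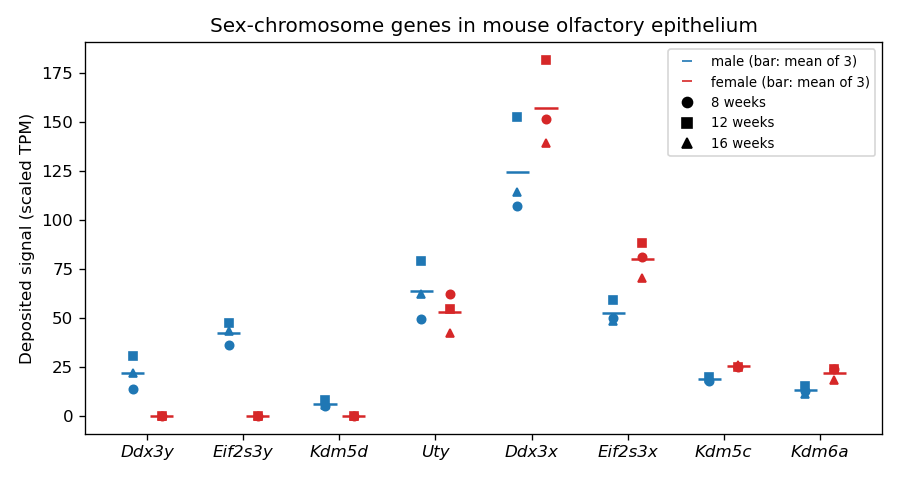
Signal of 4 Y-annotated and 4 X-linked genes in the mouse libraries, with males and females side by side, symbols for age and a bar at the mean of 3. Ddx3y, Eif2s3y and Kdm5d are at 0 in every female library, while Uty is at 42.4 to 62.3.

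No other mouse gene passed between the sexes, and the genes of smallest p in each direction among those with a mean of at least 10 in either sex, a value above 0 in every library and no overlap between the sexes are given as values. C1s1, a complement protease, had 36.2 ± 9.76 in males and 19.7 ± 5.41 in females. Rabgef1, a Rab5 exchange factor, had 46.3 ± 8.53 and 25.1 ± 4.11, and Celf4, an RNA-binding protein of neurons, 63.7 ± 22.2 and 30.8 ± 16.6. Ctbp2, a transcriptional corepressor, had 32.8 ± 2.78 and 21.2 ± 1.70, and the receptor Olfr328 22.2 ± 3.65 and 13.4 ± 1.47. The receptors Olfr1295, Olfr912 and Olfr211 had female means of 12.1 ± 0.641, 11.8 ± 2.72 and 15.6 ± 1.68, and male means of 7.07 ± 0.361, 6.45 ± 0.530 and 9.99 ± 1.10 (SD, n = 3). The receptor Olfr910, under that mean, had the smallest p of the odorant receptors, at 4.03 ± 0.386 in males and 9.33 ± 0.966 in females.

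By list, 8 of 33 differed between the sexes by camera with the preset correlation, 4 higher and 4 lower in males, and 0 did so with an estimated correlation. All 16 tested genes of antigen presentation, such as H2-Aa with 104.1 ± 20.1 in males and 78.6 ± 23.1 in females, had a positive difference, with a median of 0.29 (camera adjusted p = 4.42e-07, and adjusted p = 0.865 with an estimated correlation). Adjusted over the list alone, 0 of them passed. Of bone and cartilage genes 14 of 15 were lower in males (median -0.34, camera adjusted p = 1.85e-06, and adjusted p = 0.865 with an estimated correlation). Of trace amine-associated receptors 8 of 9 were lower (median -0.26, camera adjusted p = 0.000529, and adjusted p = 0.865 with an estimated correlation). Of odorant receptors 532 of 774 were lower, with a median of -0.09 (camera adjusted p = 2.15e-05, and adjusted p = 0.865 with an estimated correlation). That median became 0.00 when each library was rescaled to the same total, which moves all genes of a library together. All 8 lists, odorant receptors among them, were still called after this rescaling. That is no separate support, since camera compares a list with the other genes and a shift common to all largely cancels. The other called lists were the lipocalins (median 0.38, adjusted p = 0.0156), neutrophil genes (median 0.23, adjusted p = 0.0285), 3 tested skeletal muscle genes (median -0.18, adjusted p = 0.0494), and the sex chromosome list (adjusted p = 0.0285), whose median was -0.05 while its mean of 1.36 and its test were positive. Each of these had an adjusted p = 0.865 with an estimated correlation. Of the 11 tested lipocalins 7 were higher in males. Lcn4, the member of smallest p, had 17.1 ± 12.9 in males and 1.91 ± 1.79 in females (SD, n = 3). It was the 1 member that passed adjusted over the list alone, against 0 over all genes. The lipocalin sum went the other way, at 6044 ± 3051 in males and 40579 ± 67901 in females, with 118984 in the 12-week female. With age as a factor, which compares the sexes within each age, 6 of these 8 lists were called, without skeletal muscle and the sex chromosome list. After correction for GC content and length 5 of the 8 were called, without neutrophil genes, odorant receptors and the sex chromosome list. The skeletal muscle call was also lost with a pseudocount of 0.1, under median-ratio scaling and with age left out, and the lipocalin call with no filter on low values (median -0.02). With a value of at least 1 required in every library, neutrophil genes and lipocalins lost their call, skeletal muscle was not tested, and the sex chromosome list turned negative (median -0.40) as Ddx3y, Eif2s3y and Kdm5d left it.

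Most of these list differences depended on single libraries. Without the 8-week male the calls of antigen presentation (median -0.01), neutrophil genes (0.00), odorant receptors (-0.01), trace amine-associated receptors (-0.09) and lipocalins (0.81) were lost, and that of skeletal muscle with them. Antigen presentation also lost its call without the 8-week female (0.12) and had 0.49 without the 12-week male and 0.45 without the 16-week female. Bone and cartilage lost it without the 12-week male (-0.14) and had -0.17 without the 16-week female. Odorant receptors lost it without the 16-week male (-0.05) or the 12-week female (-0.08), and had -0.14 without the 12-week male. Neutrophil genes lost it without the 16-week male (0.04) or the 12-week female (0.07), and had 0.50 and 0.40 without the 12-week male and the 8-week female, and 0.34 without the 16-week female. Lipocalins lost it also without the 12-week male, the 8-week female (-1.01) or the 16-week female (-1.06), and had 2.004 and 0.97 without the 12-week female and the 16-week male. Trace amine-associated receptors had -0.17 without the 8-week female. Skeletal muscle lost its call or had too few tested genes without each library but the 16-week male, with medians from -0.39 to 0.036. The sex chromosome list lost its call without the 16-week female (-0.18), and without any male its test turned negative as the Y genes Ddx3y, Eif2s3y and Kdm5d left it.

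With age in mouse, genes of the immature olfactory sensory neuron were lower at 16 than at 8 weeks. All 15 tested members had a negative change, with a median of -0.43 (camera adjusted p = 6.40e-09, and adjusted p = 0.690 with an estimated correlation). Dpysl3, a collapsin response mediator of growing axons, went from 53.2 ± 3.44 at 8 weeks over 37.8 ± 0.0087 to 30.1 ± 0.698 at 16 weeks (SD, n = 2 per age). Adjusted over the list alone, 4 members passed, which were Dpysl3, Dpysl5, Crmp1 and the growth cone protein Gap43, the last 3 named after their values were seen. Adjusted over all genes, 0 passed. Of the 20 progenitor and cell cycle genes 17 had a negative change (median -0.43, camera adjusted p = 4.96e-06, and adjusted p = 0.861 with an estimated correlation), and without the 8-week female library the median was -0.27. Ezh2, the methyltransferase of the Polycomb complex, was the member of smallest p, at 16.9 ± 0.444, 13.2 ± 2.38 and 10.8 ± 1.84 at 8, 12 and 16 weeks. The mean of the list, relative to all 6 libraries, was 0.23 and 0.28 in the 8-week male and female, -0.11 and -0.20 at 12 weeks and -0.10 and -0.10 at 16 weeks, so it was not lower at 16 than at 12 weeks in either sex. The mature neuron list was not called (14 of 24 positive, median 0.08, camera adjusted p = 0.235), and Omp stood at 3413 ± 955 at 8 weeks and 3143 ± 74.5 at 16 weeks. Transcripts of the mitochondrial genome made up 7.10% and 6.94% of the signal in the 8-week male and female, 6.56% and 5.68% at 12 weeks, and 5.37% and 5.37% at 16 weeks.

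**Figure D3:**
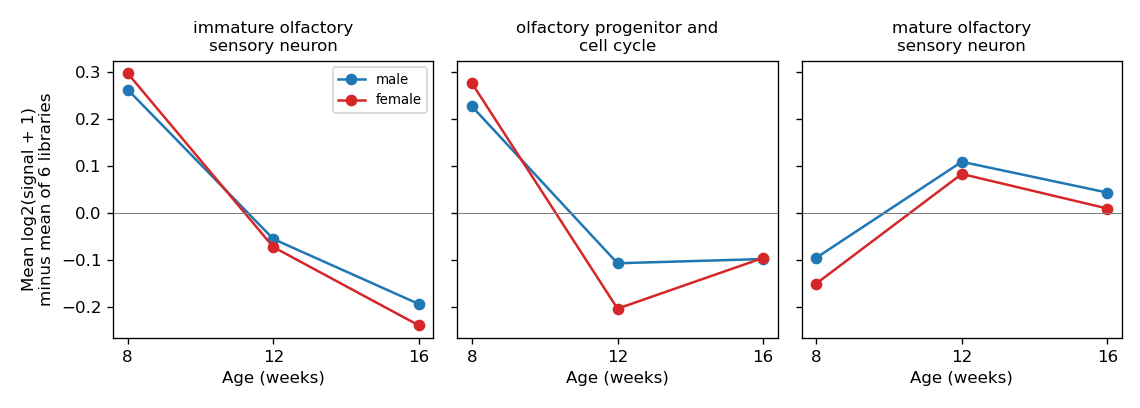
Mean log2(signal + 1) of 3 marker lists in each mouse library, minus the mean over the 6 libraries, against age in weeks, with 1 line per sex and 1 library per point. The immature list is highest at 8 weeks in both sexes and lowest at 16 weeks.

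Heat shock and stress genes were higher at 16 weeks for 16 of 18 (median 0.32, camera adjusted p = 3.09e-06, and adjusted p = 0.690 with an estimated correlation). Hspa5, a chaperone of the endoplasmic reticulum, had 467.8 ± 134.2 at 8 weeks and 959.9 ± 23.2 at 16 weeks (SD, n = 2), and 3 members passed adjusted over the list alone, against 0 over all genes. Lymphocyte and plasma cell genes were higher for 10 of 11 (median 0.54, adjusted p = 0.00239, and adjusted p = 0.861 with an estimated correlation). Xenobiotic enzymes were higher for 37 of 48 (median 0.13, adjusted p = 0.00375, and adjusted p = 0.831 with an estimated correlation). Sustentacular cells, the supporting cells of the epithelium, had 15 of 20 markers higher (median 0.13, adjusted p = 0.0390, and adjusted p = 0.755 with an estimated correlation). Several of these markers, such as Sult1c1 and Cyp2a4, are also on the xenobiotic enzyme list, so these calls are not separate results. Lower were odorant receptors, with 515 of 774 negative and a median of -0.10 that became 0.00 after correction for GC content and length, 7 of 7 erythroid genes (median -0.80), and 3 of 3 skeletal muscle genes (median -0.77). Their camera adjusted p was 0.00375, 0.00375 and 0.0112, and each had an adjusted p = 0.861 with an estimated correlation. Of all 33 lists 9 were called with the preset correlation, 4 higher and 5 lower, and 14 without the 8-week male library. The erythroid call was lost without the 8-week male (median -0.06), the lymphocyte call without the 16-week female (median 0.10), and the odorant receptor call without either 16-week library (medians -0.04 and -0.04), with quantile normalization, and after correction for GC content and length, while its median was -0.22 without the 8-week male. The xenobiotic call was lost without the 8-week or the 16-week female, and the sustentacular call without these, without the 16-week male, with age as a factor, with no filter on low values, after correction for GC content and length, and under quantile or median-ratio scaling. With tested genes held fixed, skeletal muscle lost its call without the 8-week male (median -0.53) or the 8-week female (median -0.64).

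No single mouse gene passed for age in limma (0 of 14662, smallest adjusted p = 0.0934), with 1124 genes at an unadjusted p under 0.05. The genes of smallest p in each direction among those with a mean of at least 10 over the 6 libraries, a value above 0 in each and no overlap between 8 and 16 weeks are given as values at these ages (SD, n = 2). Nr4a1, an activity-induced nuclear receptor, had 5.34 ± 0.192 and 27.0 ± 2.82, and Kirrel2, an adhesion molecule of olfactory axons, 181.7 ± 50.7 and 666.6 ± 85.3. Kcnmb3, a potassium channel subunit, had 47.1 ± 0.441 and 123.2 ± 0.633, Pacsin3 71.3 ± 3.41 and 162.7 ± 0.511, and Cyp2e1, a cytochrome P450, 26.0 ± 4.84 and 45.6 ± 8.04. In the other direction, Rpl39l, a ribosomal protein paralog, had 21.2 ± 2.41 and 4.36 ± 1.08, Ppfibp1 50.6 ± 0.670 and 21.3 ± 5.08, Slc20a2, a phosphate transporter, 29.2 ± 2.45 and 15.3 ± 1.41, and Cnpy1 19.1 ± 0.800 and 11.001 ± 0.199. With age as a factor 4 genes passed, Nr4a1 and Rpl39l among them. Without the 8-week male library 3 genes passed, and 1 passed after correction for GC content and length.

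Between the sexes in Nile rat, 5 genes were higher in males and 5 in females among 14878 tested. The 5 male genes were listed at 0 in all 3 female libraries. ENSANLG00005020523 had a male mean of 49.3 ± 1.14 and ENSANLG00005017961 59.8 ± 3.12 (SD, n = 3). Of the 5 female genes 1 was listed at 0 in all males, ENSANLG00005025591 with a female mean of 7.22 ± 0.905. ENSANLG00005022977 had 32.8 ± 4.35 in females and 0.0156 ± 0.0271 in males. These IDs lie outside the rule for named genes and were chosen after their values were seen, and gene names for them were not used here. At an unadjusted p under 0.05 there were 1193 genes. Leaving out any 1 library gave 3 to 6 calls where the filter on low values was applied again, and 8 to 12, of which 8 were among the 10, with the tested genes held fixed. With age as a factor 8 genes were called, all among the 10.

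With age in Nile rat, 2 genes rose and 0 fell among 14878 tested, with log2 changes of 2.73 ± 0.133 and 1.73 ± 0.0963 (SE, limma adjusted p = 0.0246 and 0.0261). Their means were 0.555 and 1.54 at 8 weeks, 2.55 and 3.54 at 12 weeks and 9.29 and 7.40 at 16 weeks (n = 2 per age), in the same order in each sex. With age as a factor 3 genes were called, of which 1 was among these 2. At an unadjusted p under 0.05 the linear age term gave 1943 genes. The count was 0 with a pseudocount of 0.1, with no filter on low values, and without the 8-week female, the 16-week female or the 8-week male. It was 3 without the 12-week male, with 1 shared, and with 0 shared it was 1 without the 12-week female and 9 without the 16-week male.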

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

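The tests of Bowman gland tissue and of lost signal were chosen after the results were seen. Over the 6 libraries of a species, 44 library values were checked for a sample far from the rest. Of these, 7 were past the critical value of 0.625, where chance gives about 1 in 20 for a single check. All lie in 2 libraries. The sums and shares there rest largely on the same abundant genes, so they are not separate checks. On the log2 scale, the mean of the lipocalin list in the 12-week female mouse gave 0.382, which was not past the critical value.

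In the 12-week female mouse the summed signal, in units of 1000, was 1317, the share of the 10 highest genes 27.8%, the lipocalin sum 118984 and the lipocalin share 9.03%, each far above the other 5 libraries. The 11 tested lipocalins had a median log2 difference of 4.75 to the mean of those libraries, and 8 differed by more than 1. Lcn2, Lcn4 and Lcn3 differed by -0.69, -0.32 and 0.44, and of these Lcn2 and Lcn3 were named after their values were seen. A set of 8 genes, each at 1000 or more and at least 10 times every other library, held 15.9% of its signal and at most 1.20% elsewhere. The set included Obp1a and Obp1b, and also gene models outside the lipocalin list. Only 17 of the 25 list members were found by symbol, and whether these models are lipocalins was not tested. More tissue of Bowman glands, the mucus glands of the epithelium, would bring their other transcripts too. A rise of 15 such markers together, as large as that of the lipocalins, is argued against by their median log2 difference of 0.0872. However, 3 of them, Dmbt1, Bpifb9a and Bpifb9b, named after their values were seen, differed by 1.78, 2.33 and 2.36. The mean of the Bowman gland list, relative to all mouse libraries, was also highest in this library, at 0.34 against at most 0.11 elsewhere. Some of the 15 markers also belong to the macrophage or neutrophil list, so more gland tissue is not excluded. A loss of signal in all other genes cannot be told apart from the unstated scaling, which can itself set the median gene: it differed by -0.0385 as deposited and by -0.47 at equal library totals. RNA from another nasal gland may be the source and stays untested, since 0 marker lists of such glands were fixed beforehand. With 1 library of that age and sex, a difference by age or sex stays open and untested.

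In the 8-week male Nile rat the summed signal, in units of 1000, was 1310.04, the share of the 10 highest genes 27.8%, and the number of genes with a signal of at least 1 was 14670, the lowest. A set of 7 genes held 16.2% of its signal and at most 0.526% elsewhere.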

How the results depend on the processing

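Chosen after the data were seen were rescaling, the GC content and length correction, age as a factor for the age results, fixed tested genes, and all list tests in mouse. None of the planned results between or over both species could be run. Rescaling each library to the same total called 31 genes by sex (23 higher) and 62 by age (21 higher) in mouse, and 161 (67 higher) and 263 (217 higher) in Nile rat. These counts go with a change in how the spread was estimated. Rescaling moved the median gene of the 12-week female mouse by -0.36 and of the 8-week male Nile rat by -0.36. The median residual SD rose from 0.167 to 0.308 in mouse and from 0.105 to 0.214 in Nile rat. With unlimited prior degrees of freedom, limma then gave each gene the spread of the mean-variance trend at its mean. The counts are therefore not read as more changes. Requiring a signal of at least 1 in every library gave 0 sex calls in both species, as all 3 mouse genes and 8 of the 10 Nile rat genes left the test and the other 2 missed the threshold (adjusted p = 0.0771 and 0.0818); it gave 5 lists by sex, 1 Nile rat gene by age, and a sex chromosome list median of -0.40 with a reversed direction, as its Y genes were no longer tested. For age in mouse, 4 genes were called with age as a factor and 1 after the GC correction. For age in Nile rat, 0 were called with a pseudocount of 0.1 and 0 with no filter, and 7 with quantile normalization; the cause was not tested. An estimated correlation gave 0 lists by sex and 0 by age.

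Leaving out 1 library gave 0 to 5 mouse genes by sex, where the 0 came from a male library left out and the Y genes leaving the filter; with fixed genes all 3 stayed called without any male library. It gave 0 to 3 mouse genes by age, 3 to 12 Nile rat genes by sex, 0 to 9 by age, and 6 to 14 lists by age, the 14 without the 8-week male. Medians by sex ranged from -0.013 to 0.49 for antigen presentation, 0.0039 to 0.50 for neutrophil genes, -1.06 to 2.004 for lipocalins and -0.50 to 0.019 for the sex chromosome list (0.19 at most with fixed genes), and the direction of the test reversed without the 8-week male (-0.013) for the first, without the 8-week and 16-week males (0.0039 and 0.041) for the second, without the 8-week female (-1.01) for the third, and without any male for the fourth, as Y genes left the test. The immature neuron, progenitor and heat shock lists kept their direction and call in every alternative but the estimated correlation. Over all alternatives for named genes, 2540 values were counted as unchanged. Among these, genes with a call kept call and direction, and genes without one moved by less than their spread, with no check of sign. Genes without a call could thus change sign: Dbp by sex ranged from -0.103 to 0.160 over the fits without 1 library. Another 130 values without a call moved by more than their spread, 35 lost a call and 14 gained one. Receptor thresholds other than 1 were planned for the species comparison only and were not run. The labels give no replicate numbers, and the pairing of sexes by age was kept by the fit with age as a factor, which called 3 genes by sex in mouse, 8 in Nile rat and 6 lists, all among those called with a linear age term. The GC content and length correction kept 5 of the 8 lists by sex and 7 of the 9 by age. Read depth is unknown, so what it limits could not be judged.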

Other observations

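The tests of age assignments for single lists, of neuronal tissue, of male material and of the GC content and length gradients across splits were chosen after the results were seen, and the counts without a sex term were added later still.

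Clock genes were measured in every mouse library. Dbp, a clock-driven transcription factor, had 27.9 ± 3.48 in males and 27.4 ± 4.25 in females, Nr1d1, a repressor of the clock loop, 18.7 ± 3.58 and 17.2 ± 1.24, Arntl, the gene of BMAL1, 8.50 ± 0.192 and 8.92 ± 0.635, and Per1 12.8 ± 1.91 and 12.5 ± 3.55 (SD, n = 3). The clock list was called neither by sex nor by age (camera adjusted p = 0.738 and 0.461), and the time of sampling is not given in the labels. Lists of respiratory ciliated cells, ensheathing glia, horizontal basal cells, vomeronasal neurons, macrophages and steroid hormone genes were not called in either comparison.

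The immature neuron and progenitor lists, lower at 16 than at 8 weeks, could be technical, but GC content and length bias is argued against, since the smaller ratio of corrected to uncorrected median change was 0.984. For the immature list, a smaller share of neuronal tissue in older samples is argued against by the mature list, whose slope lay above by 3.97 standard errors (3 residual degrees of freedom). The progenitor list was not compared in this way. The mature list itself was mixed, with 14 of 24 positive and Kirrel2 at a log2 change of 1.89, and 515 of 774 odorant receptors were negative. Chance is not excluded: 5 of the 45 assignments of ages to libraries gave a slope as large as 0.497 for the immature list (highest other 0.752), and 10 of 45 one as large as 0.349 for the progenitor list (highest other 0.624). Assignments that tie age to sex inflate slopes in a model with sex; without the sex term the counts were 1 and 6 of 45, and with ages permuted within each sex 1 and 4 of 18, but the immature list was singled out as the strongest of 33. A change with age stays open as a hypothesis, as does sample quality, which was not tested as a cause (mitochondrial share 7.10% and 6.94% at 8 weeks and 5.37% in both sexes at 16 weeks, rho of the age change with transcript length across genes -0.285, heat shock list higher at 16 weeks).

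For the number of lists called with age, 35 of the 45 assignments gave at least the real 9 (highest other 17), and 34 did so without the sex term, so chance is not excluded for that count. For the Nile rat age genes, 2 of 45 gave the real 2 (highest other 2), and without the sex term 5 genes were called and 1 of 45 gave as many. Most of the 45 tie age to sex, unlike the real ages, so these counts do not exclude chance. Ages permuted within each sex keep the balance, and 1 of 18 gave as many (highest other 1), too few for a share under 0.05. Both calls were lost in 5 of the 6 fits that left out 1 library. Sex has 10 splits of 6 libraries, too few for a share under 0.05. The Nile rat gave 10 genes in 1 split, against 2 in the highest other. The mouse lists gave 8, with 7 splits as large and 13 in the highest other. The mouse genes gave 3, with 2 splits as large, the other calling 2305.

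That split points to a structure of the mouse samples. The first principal component, the axis of largest spread with 40.2% of the variance, divided the libraries in the same way. Sex took 13.3% of the variance and age 21.9%, where chance gives 20% per term, and 64.9% was left over. The split sets the 8-week male and both 16-week libraries, whose deviations correlated with GC content across genes at rho 0.377 to 0.457, against the 8-week female and both 12-week libraries, at -0.508 to -0.283, and transcript length divided them the same way, at -0.419 to -0.292 against 0.216 to 0.490. After the GC content and length correction it called 29 genes, which does not separate GC content from length, and the split by sex still called 3, while 3 of the 8 lists by sex and 2 of the 9 by age lost their call. These gradients are unevenly spread over sex and age: the sex difference correlated with GC content at rho 0.317 and with length at -0.106, and the age change at 0.261 and -0.285. In Nile rat it was not tested, since transcript sequences were not used here.

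Uty, annotated on the Y chromosome, had a signal of 42.4 to 62.3 in the female mouse libraries. Male material in them is argued against, since the largest Ddx3y, Kdm5d or Eif2s3y value in a female library was 0. Sequence shared with other genes could contribute and cannot be told apart from other sources: at most 12.23% of the 31-base words of a Uty transcript, a retained intron form, occur in another gene, and at most 1.65% for a protein-coding one. Its values overlapped between males and females and did not pass between the sexes, and no biological explanation of its female signal was tested.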
